A study of Mus musculus with 6 samples.

How the data were processed

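RNA was sequenced from macrophages of regenerating mouse skeletal muscle. The cells carried CD11b and F4/80 and little Ly6C, and had been sorted 3 days after injury with barium chloride. Per the labels, 3 libraries came from young and 3 from old wild-type mice, and RNA was extracted with a micro-scale column kit. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

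The values used were FPKM (fragments per kilobase of gene, scaled to library size), which the authors had computed per gene and deposited as 1 table of 54966 features by 6 libraries. The genome build was GRCm38.p6, per the submitters' processing notes. The aligner, the counting tool, the strandedness and the annotation release are not given in the sources used here. No raw counts were used. Gene identifiers were matched to GENCODE release M21 on GRCm38, which held 54495 of them (99.14%). The release may differ from the one the authors used. Symbols that had turned into dates (27) or dashes (434) were taken from the annotation through the identifier, and features without an annotated identifier were kept under their own identifier.

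Depth was estimated from the FPKM steps. FPKM multiplied by the exon-union length of each gene gave whole multiples of 1 fragment, within a tolerance of 0.02 and for multiples below 200, in 97.5% to 97.6% of the values per library. Totals of recovered fragments lay between 16524983 and 19381663 per library. The denominators implied by the FPKM differed from these totals, and they tracked a trimmed-mean composition factor to within 0.022 on the log2 scale. CPM are recovered fragments relative to these denominators.

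The comparison was old against young, with all 6 libraries. Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and a mean-variance trend, for the 11108 genes with a mean of at least 1 FPKM. P-values were two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Every log2 change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. Gene lists were tested with camera from limma, with a preset correlation of 0.01 between genes and adjustment over the 37 lists with at least 5 tested members. Members of a list were also counted with adjustment over the list alone. Manf was tested in addition with an exact two-sided permutation test, which cannot go below p = 0.1 with 3 libraries per group.

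The design, the gene lists, the rule for naming genes and the alternative settings listed first below were chosen before the data were examined. The rule named, in each direction, the 12 protein-coding genes with non-overlapping groups that passed the threshold and had the largest change, leaving out symbols of provisional gene models. Where fewer than 12 passed, those with the smallest unadjusted p followed and are described as not passing. It also named up to 4 members of smallest p in each list described, and every member of the lists for gate and surface markers, sex-linked genes and Manf. Names outside the rule were chosen after their values were seen. These are the features without a rule-conforming symbol that passed, the highest feature of each library, the further list members given as examples or exceptions, and the genes named in the additional observations.

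The alternative settings were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, median-of-ratios and quantile scaling, rescaling to TPM, limma without the trend, robust moderation, array weights, the replicate number as a block, each library left out in turn, and, for lists, an estimated correlation and fry. Added after the data were seen were limma voom on the recovered fragments and a threshold of 0.1. The fits were tested on simulated data for the 11108 genes, with normal noise drawn independently at each gene's moderated spread. Of genes changed by 0.5, 1 and 2 on the log2 scale, 56.7%, 86.6% and 100% were called, and 7 of 169 calls were false. The moderated spread varies less between genes than the observed one, so changes of these sizes can be called less often in the real data. There, Mmp9 at a log2 change of -2.29 did not pass (limma adjusted p = 0.093). With the 52 lysosome genes alone shifted by 0.2 and genes drawn independently of each other, camera called that list (adjusted p = 7.9e-22) and 2 other lists of 37, lipid handling (adjusted p = 0.0372) and cell cycle inhibitors and senescence (adjusted p = 0.0246). Only 3 of 26 and 1 of 23 tested genes of these 2 lists belong to the lysosome list, and their other genes were not shifted.

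Random lists of genes matched on length or GC content and on mean expression (10000 draws, with the range of the central 95% of their medians) were used for the tests of the additional observations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. Some items are not reported here.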

Results

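The data describe macrophages that take part in muscle repair in young and old mice. The cells were gated as CD11b-positive, F4/80-positive and Ly6C-low, a profile of pro-repair macrophages, 3 days after barium chloride injury, a chemical injury that destroys fibres and starts regeneration. Each group had 3 libraries, with 18332838, 16524983 and 16978888 recovered fragments in young replicates 1 to 3 and 18727990, 17870883 and 19381663 in old. Macrophage transcripts were abundant in both groups. The highest feature was the provisional gene model Gm23935 in the young libraries and old replicate 2 (11380.3 to 15087.9 FPKM), and Apoe in old replicates 1 and 3. Lyz2 reached 10360 FPKM in young and 9916 in old, C1qb 2253 and 2509, and Adgre1, which encodes F4/80, 362 and 446. Pairs of libraries within a group correlated at r = 0.981 to 0.988 across genes, which are not independent replicates, and pairs between groups at 0.976 to 0.986. The first principal component held 36.4% of the variance and placed the 3 young libraries on one side of the 3 old ones. On it, young replicate 1 (-1.96) lay nearer to old replicate 2 (6.18) than to young replicates 2 (-12.89) and 3 (-20.19). Young replicate 1 also correlated best with old replicate 2 (r = 0.9859, against 0.9846 and 0.9813 with young replicates 2 and 3).

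The first question was which single genes differed between the young and old libraries. Actc1, the cardiac alpha-actin that is also made in developing muscle, fell from 1.91 ± 0.197 to 0.126 ± 0.0839 FPKM (SD, n = 3 per group), a log2 change of -1.37 (SE 0.125, limma adjusted p = 0.0444). The gene lies on chromosome 2, from 114047282 to 114053548, and its old libraries held 1 to 6 fragments against 50 to 58 in young. Tspan13, which encodes a tetraspanin membrane protein (chromosome 12, 36014557 to 36042500), fell from 50.3 ± 2.28 to 31.0 ± 1.08 FPKM, a log2 change of -0.68 (SE 0.065, limma adjusted p = 0.0444). Higher in old were the processed pseudogene Gm15433 (chromosome 1, 84963669 to 84964559), with 0.145 ± 0.137 FPKM in young and 2.87 ± 0.18 in old, and a feature with no annotated identifier, with 0.0358 ± 0.0619 and 2.9 ± 0.281 FPKM. Their log2 changes were 1.76 (adjusted p = 0.0127) and 1.91 (adjusted p = 0.00875), and fragments of a pseudogene can be shared with its parent gene. Both fall outside the naming rule and were chosen after their values were seen. Both were nearly absent from every young library, and age cannot be told apart here from any other difference between the groups of mice. Actc1 is a muscle gene, and the marker list of muscle fibres was also lower in old, with a median log2 change of -0.45 over 7 tested members, of which 2 passed over the list alone. Camera called that list (adjusted p = 0.0016), and the call was lost with an estimated correlation (adjusted p = 0.326 with an estimated correlation).

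These 4 were the calls among 11108 tested genes, 2 higher and 2 lower. At an unadjusted p under 0.05, limma gave 1668 genes, 982 higher and 686 lower, where 555 are expected by chance. The groups did not overlap in 20.9% of genes, against 10% by chance. No gene passed with a pseudocount of 0.1 or 0.01, without the filter, with a minimum of 5 FPKM, or without any 1 of 5 libraries, while 6 and 9 passed without young replicate 1. Array weights gave 30 higher and 20 lower.

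The next genes by p did not pass and were separated between groups in every library. Among those with higher values in old were Siglec1, which encodes the macrophage lectin sialoadhesin, with 72.4 ± 12.6 FPKM in young and 133.9 ± 4.92 in old (log2 change 0.89, SE 0.126, limma adjusted p = 0.0826), and the monocyte-attracting chemokine gene Ccl12, with 41.8 ± 7.09 and 81.1 ± 7.68 FPKM (0.95, adjusted p = 0.0826). Cpt1a, whose product admits fatty acids to mitochondria, had 37.7 ± 1.43 and 52.6 ± 2.16 FPKM (0.47), and Smpdl3a, of the acid sphingomyelinase family, had 108.6 ± 9.82 and 174.6 ± 14.5 FPKM (0.68). The others in this direction were Cd200r4 (0.62), Vps13c (0.58), Shtn1 (0.91), Eya4 (1.13), Arhgef18 (0.77), B3galnt1 (0.46), Psen2 (0.45) and Irgm2 (0.43), with adjusted p from 0.0609 to 0.0826. With lower values in old were Acp5, which encodes tartrate-resistant acid phosphatase, with 118.7 ± 23.9 and 60.6 ± 1.41 FPKM (-0.94, adjusted p = 0.0826), and Runx3, a transcription factor, with 26.7 ± 2.47 and 17.0 ± 1.45 FPKM (-0.62, adjusted p = 0.0826). The DNase gene Dnase1l3 had 9.26 ± 2.97 and 2.82 ± 0.647 FPKM (-1.40, adjusted p = 0.088). Pxdc1 (-0.83), Cd244a (-0.52), Vipr1 (-0.96), Adgrg5 (-0.86), Ccdc102a (-0.68), Hap1 (-0.62) and Ocstamp (-0.68) completed the list.

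**Figure D1:**
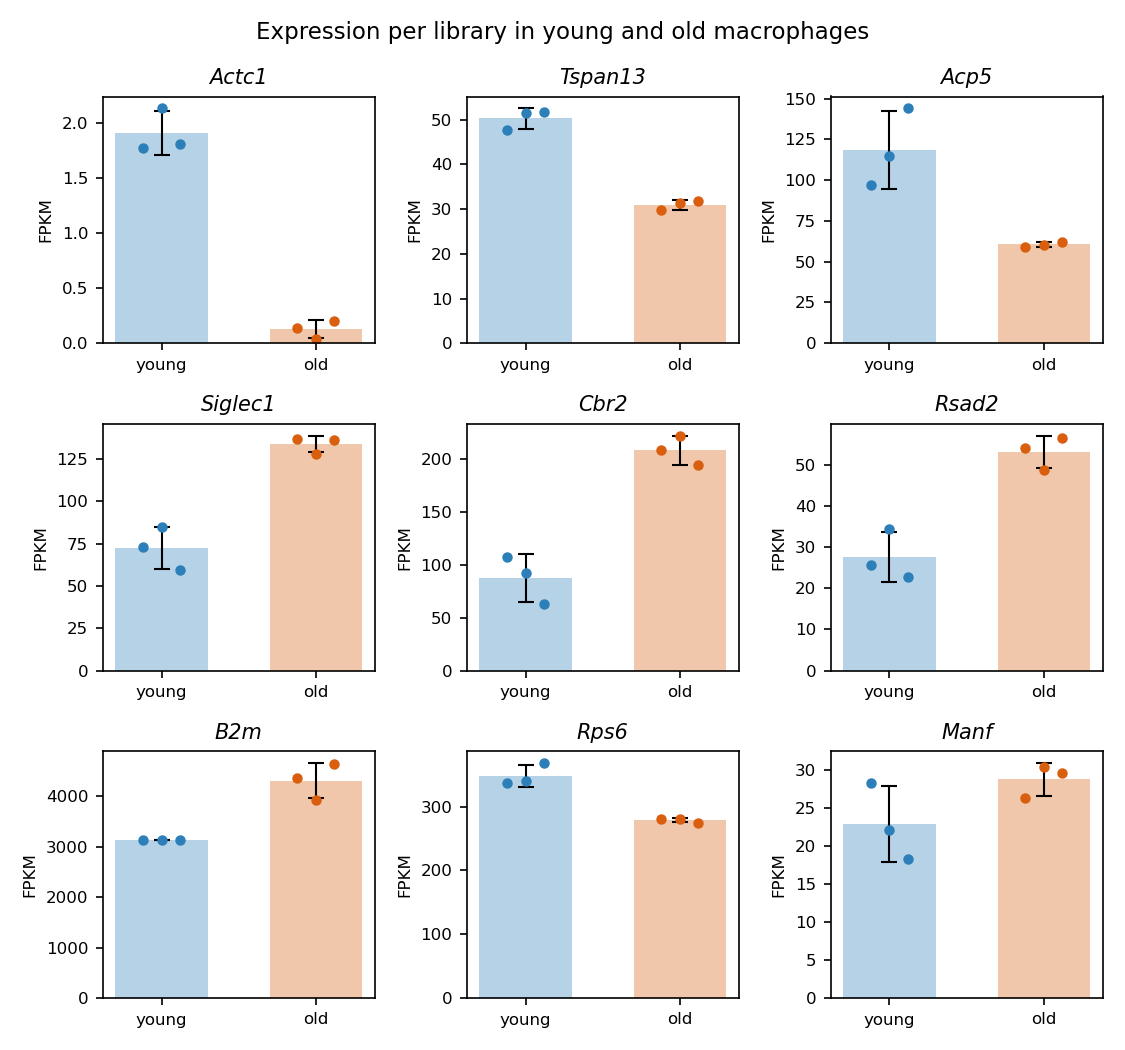
FPKM (vertical axes, each starting at 0) of 9 genes in the 3 young and 3 old libraries, with bars for means, error bars for the SD and points for single libraries. Actc1 and Tspan13 passed the threshold over all genes and the others did not, and for Manf the young libraries span 18.3 to 28.2 FPKM and the old ones 26.3 to 30.4.

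The next question was whether groups of genes differed together. Of the 37 lists tested with camera, 11 were called higher and 3 lower in old. No list passed with an estimated correlation, where the smallest adjusted p was 0.326, and 1, phagocytosis, passed fry (adjusted p = 0.0357). The correlation estimated between members was -0.001 for phagocytosis, 0.599 for type I interferon, 0.641 for ribosomal proteins and 0.887 for mitosis. Members of the latter lists are not independent, so many members with the same sign weigh less than their number. For phagocytosis the estimate lay below the preset 0.01, so correlated members do not account for its lost call. No list had a member past the threshold over all genes.

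Genes of the type I interferon response, the antiviral programme, were higher in old with a median log2 change of 0.39. All 37 members had positive changes, 28 were higher adjusted over the list alone and 0 over all genes. Camera gave an adjusted p = 1.56e-17, and adjusted p = 0.387 with an estimated correlation. Rsad2, which encodes viperin, had 27.6 ± 6.01 FPKM in young and 53.1 ± 3.98 in old (log2 change 0.94, SE 0.147). Cmpk2 had 14.8 ± 2.21 and 24.4 ± 0.654 FPKM (0.70), Ifit1 14.7 ± 2.95 and 23.4 ± 0.199 FPKM (0.66), and Usp18 18.0 ± 2.99 and 28.6 ± 2.95 FPKM (0.65). MHC class I antigen presentation was called higher as well (median 0.35, adjusted p = 9.04e-09, and adjusted p = 0.326 with an estimated correlation). Of its 20 members, 11 were higher adjusted over the list alone and 0 over all genes. B2m, the invariant light chain, had 3133 ± 4.36 FPKM in young and 4312 ± 352 in old (0.46), H2-D1 had 1032 ± 13.1 and 1519 ± 203 FPKM (0.55), and the peptide transporter gene Tap1 had 26.0 ± 2.81 and 34.5 ± 2.19 FPKM (0.40). H2 genes have near-identical copies, so the division of fragments among them is uncertain. The interferon gamma list was not called (adjusted p = 0.0874), but was called higher without young replicate 2 (adjusted p = 0.00117), without old replicate 2 (adjusted p = 0.015) and when rescaled to TPM (adjusted p = 0.0321). MHC class II, not called at a median of -0.24 (adjusted p = 0.107), was called lower without old replicate 1 (adjusted p = 0.00096), without young replicate 1 (adjusted p = 0.0152) and under 4 other settings.

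Lysosomal genes were higher in old with a median log2 change of 0.22 (adjusted p = 2.71e-08, and adjusted p = 0.326 with an estimated correlation). Of 52 members, 25 were higher and 2 lower adjusted over the list alone, and 0 passed over all genes. Lamp2, a membrane protein of lysosomes, had 73.3 ± 1.03 and 89.7 ± 3.2 FPKM (0.29, SE 0.061). Glb1, the lysosomal beta-galactosidase, had 51.0 ± 0.898 and 65.7 ± 4.81 FPKM (0.36), and Npc1, which exports cholesterol from lysosomes, had 33.9 ± 1.78 and 43.6 ± 3.34 FPKM (0.35). Acp5 (-0.94) and Ctsk (-0.48) were the 2 lower members.

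Phagocytosis and clearance of dead cells was called higher (median 0.18, adjusted p = 0.000257, and adjusted p = 0.326 with an estimated correlation), with 2 of 39 members higher adjusted over the list alone and 0 over all genes. These were Gas6, a bridge between dying cells and phagocyte receptors, with 104 ± 5.99 and 146.3 ± 10.5 FPKM (0.49), and Dock2 with 26.9 ± 1.34 and 33.2 ± 0.994 FPKM (0.30). Lipid handling was called higher (median 0.17, adjusted p = 0.00508, and adjusted p = 0.545 with an estimated correlation). Its 2 of 26 members that passed over the list alone were the lipid droplet gene Plin2, with 319.5 ± 30.5 and 497.9 ± 62.0 FPKM (0.64), and Npc1. The call was lost without old replicate 3 (adjusted p = 0.0661). Complement was called higher (median 0.23, adjusted p = 0.000257, and adjusted p = 0.483 with an estimated correlation), with 6 of 16 members higher over the list alone, among them C4b (0.98), C1ra (0.50) and C3ar1 (0.42). ER stress and the unfolded protein response was called higher (median 0.22, adjusted p = 0.00129, and adjusted p = 0.646 with an estimated correlation), with 20 of 25 members positive and 0 passing over the list alone. Its smallest p values belonged to Herpud1, which went the other way (-0.48), Sel1l (0.25), Pdia4 (0.50) and Ddit3 (0.32).

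Repair-associated macrophage markers were called higher (median 0.20, adjusted p = 0.00319, and adjusted p = 0.326 with an estimated correlation). Adjusted over the list alone, 7 of 27 were higher and 1, Cx3cr1 (-0.49), was lower, with 0 over all genes. Gdf3, a TGF-beta family ligand, had 20.0 ± 12.9 FPKM in young and 82.7 ± 18.2 in old (2.13, SE 0.381, limma adjusted p = 0.134), and Lyve1, a hyaluronan receptor of resident macrophages, 1.31 ± 0.575 and 7.87 ± 3.54 FPKM (1.89, SE 0.303, limma adjusted p = 0.0951). Growth and trophic factors were called higher (median 0.22, adjusted p = 0.0439, and adjusted p = 0.534 with an estimated correlation), with 6 of 25 higher and 1 lower over the list alone. Pdgfc had 2.22 ± 0.235 and 3.98 ± 0.559 FPKM (0.62), Hgf, which activates muscle stem cells, 9.81 ± 1.27 and 13.9 ± 0.59 FPKM (0.47), Igf1 13.9 ± 0.45 and 17.5 ± 1.27 FPKM (0.31), and Pdgfb, the lower member, 11.9 ± 2.22 and 6.01 ± 1.93 FPKM (-0.89). That call was lost without young replicate 2 (adjusted p = 0.0947), old replicate 1 (adjusted p = 0.197) or old replicate 3 (adjusted p = 0.0661), with either smaller pseudocount (adjusted p = 0.0576 and 0.0604), without the filter (adjusted p = 0.0922), with a minimum of 5 FPKM (adjusted p = 0.0738) and under quantile normalization (adjusted p = 0.103).

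Markers of other macrophage states were also called higher. Resident tissue macrophage markers were called higher (median 0.41, adjusted p = 4.54e-06, and adjusted p = 0.326 with an estimated correlation), with 8 of 16 higher over the list alone. Cbr2 had 87.4 ± 22.7 and 208.2 ± 13.7 FPKM (1.27, SE 0.187, limma adjusted p = 0.0826). Cd209f had 0.283 ± 0.2 and 1.74 ± 0.763 FPKM (1.06), and Selenop, the most abundant member, had 1350 FPKM in young and 995 in old. Lyve1, Folr2, Cd163 and Igf1 belong to this list and to that of repair markers. Gas6 (0.49) and C4b (0.98) also passed over the resident list alone. Gas6 is a member of the phagocytosis list as well, C4b of complement and Igf1 of growth factors. The call of the resident list is therefore not separate evidence from the calls of those lists. Markers of Ly6C-high monocytes were called higher (median 0.41, adjusted p = 0.0181, and adjusted p = 0.326 with an estimated correlation), with 4 of 17 higher over the list alone. These were Ly6a (1.54), Gda (0.71), Ms4a4c (0.60) and Ifi204 (0.43), while Ccr2, the chemokine receptor of inflammatory monocytes, had 37.6 and 24.9 FPKM (-0.55, SE 0.231). The monocyte call was lost without young replicate 1 (adjusted p = 0.151), with array weights (adjusted p = 0.139) and with a minimum of 5 FPKM (adjusted p = 0.059).

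Cytosolic ribosomal protein genes were lower in old with a median log2 change of -0.26. All 75 had negative changes, 39 were lower adjusted over the list alone and 0 over all genes. Camera gave adjusted p = 1.61e-26, and adjusted p = 0.387 with an estimated correlation. The 39 all stood at a limma p adjusted over the list alone of 0.0431 or 0.0432, so they pass together and narrowly. Rps6 had 348.3 ± 17.4 and 279 ± 3.71 FPKM (-0.32, SE 0.071), Rplp0 705.4 ± 45.9 and 549.4 ± 25.4 FPKM (-0.36), and Rpl10a 166.3 ± 13.1 and 128.6 ± 8.72 FPKM (-0.37). Many of these genes have processed pseudogenes, so fragments can be shared among copies. Mitosis genes were called lower (median -0.28, adjusted p = 0.00013, and adjusted p = 0.7 with an estimated correlation). Of 28 members 28 were negative and 0 passed over the list alone. The groups did not overlap for 1 of the 28, and fry gave adjusted p = 0.557. At an estimated correlation of 0.887 between members, the 28 signs are not 28 separate observations. Cenpa, a centromeric histone, had 8.77 ± 0.414 and 6.56 ± 0.682 FPKM (-0.37), and Ccnb2, a mitotic cyclin, 28.2 ± 3.77 and 20.0 ± 6.55 FPKM (-0.52). The call was lost without old replicate 3 (adjusted p = 0.192), and genes of DNA replication were not called (median -0.07, adjusted p = 0.239). The replication list was called lower without young replicate 3 (adjusted p = 0.00028), without old replicate 2 (adjusted p = 0.00255) and with array weights (adjusted p = 0.0299).

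Transcripts of muscle fibres were low in all libraries and lower in old (median -0.45, adjusted p = 0.0016, and adjusted p = 0.326 with an estimated correlation). Of 7 tested members 2 were lower over the list alone. These were the skeletal alpha-actin gene Acta1, with 5.26 ± 1.26 and 2.33 ± 0.866 FPKM (-0.93), and the troponin gene Tnni2, with 3.91 ± 0.183 and 2.31 ± 0.488 FPKM (-0.58). Without the filter the call was lost (adjusted p = 0.0571), and the fibroblast list, not called at the minimum of 1 FPKM (adjusted p = 0.131), was then called lower (adjusted p = 1.76e-06), as it was without young replicate 3 (adjusted p = 0.0289). Markers of endothelial cells (adjusted p = 0.239), neutrophils (adjusted p = 0.368), dendritic cells (adjusted p = 0.947) and the macrophage identity list (adjusted p = 0.131) were not called, and the last was called higher without young replicate 3 (adjusted p = 0.0354) and without the filter (adjusted p = 0.0415). Too few members were tested for T and NK cells (3), B and plasma cells (2), eosinophils and mast cells (2), mural cells (2), myoblasts (2) and erythroid cells (1). In these groups Cd4 had 8.13 and 2.85 FPKM, Ighm 36.2 and 15.7 FPKM, Acta2 2.52 and 1.11 FPKM, and Myog 2.12 and 0.746 FPKM in young and old, each lower over its list alone. Ear2 had 3.46 and 6.79 FPKM and Bpgm 1.69 and 1.78 FPKM and did not pass.

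**Figure D2:**
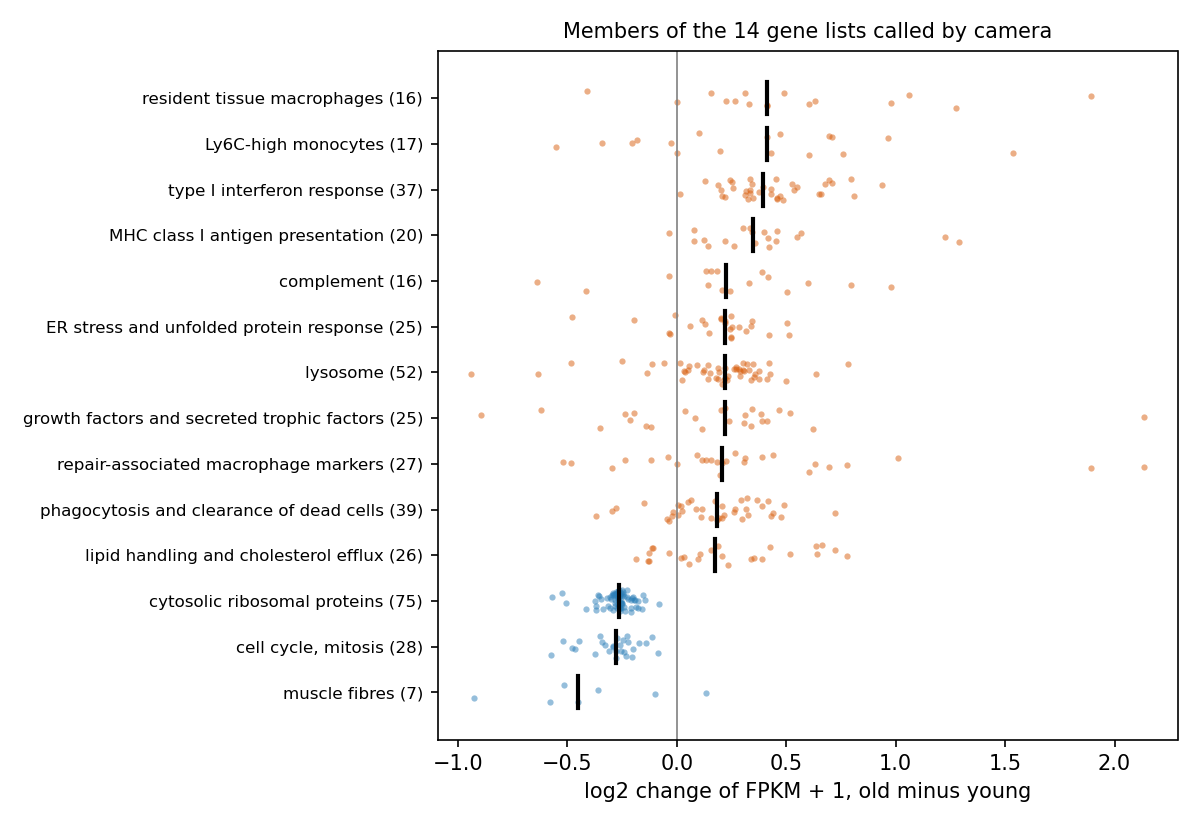
Log2 change of FPKM + 1, old minus young (horizontal axis), of the tested members (points, with their number in parentheses) of the 14 lists called by camera, with a black line at each median. All 37 type I interferon genes lie above 0 and all 75 ribosomal protein genes below 0. Members of these lists are correlated (estimates of 0.599 and 0.641), so their signs are not independent.

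Several lists were not called and held members that passed over the list alone. Of 27 chemokine and receptor genes (adjusted p = 0.311), 7 were higher and 2 lower. Ccl8 had 86.9 ± 19.5 and 334.6 ± 178.8 FPKM (1.83), Ccl6 101.5 ± 11.5 and 185.5 ± 27.6 FPKM (0.86), and Cxcl14 3.25 ± 0.57 and 1.76 ± 0.277 FPKM (-0.62). Of 22 genes of extracellular matrix and remodelling (adjusted p = 0.359), 3 were higher and 6 lower. The gelatinase gene Mmp9 had 13 ± 6.23 and 1.72 ± 0.757 FPKM (-2.29, SE 0.364, limma adjusted p = 0.093), Sparc had 2.48 ± 0.78 and 0.83 ± 0.0283 FPKM (-0.90), and Timp2 167 ± 12.6 and 217.9 ± 8.54 FPKM (0.38). This list's median was 0.07 and its mean -0.11. Of 30 adhesion genes (adjusted p = 0.436), 3 were higher and 4 lower, among them Itgal (-0.84) and Pecam1 (-0.53). Hpgd, which degrades prostaglandins, was the 1 eicosanoid gene of 20 (adjusted p = 0.904) that passed over the list alone, with 36.7 ± 17.5 and 8.03 ± 1.73 FPKM (-1.97). Of 21 oxidative stress genes (adjusted p = 0.0626), 3 were lower, Gsr (-0.45), Slc7a11 (-0.53) and Cat (-0.26). That list was called lower without young replicate 3 (adjusted p = 0.0289), without old replicate 2 (adjusted p = 0.0339) and under 3 other settings, the chemokine list was called higher with a minimum of 5 FPKM (adjusted p = 0.038), and the matrix list lower without the filter (adjusted p = 0.0114).

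Inflammatory macrophage genes showed no call (median -0.06, adjusted p = 0.3), with 0 of 31 members passing over the list alone. The list was called lower without old replicate 1 (adjusted p = 0.000513), without young replicate 1 (adjusted p = 0.0255) and with array weights (adjusted p = 0.0248). Nor were called oxidative phosphorylation (adjusted p = 0.239), mitochondrially encoded transcripts (adjusted p = 0.107), glycolysis and hypoxia (adjusted p = 0.368), cholesterol synthesis (adjusted p = 0.987), iron handling (adjusted p = 0.878), autophagy (adjusted p = 0.368), cell cycle inhibitors and senescence (adjusted p = 0.368), nuclear-retained RNA (adjusted p = 0.362) and the immediate early genes that tissue dissociation induces (adjusted p = 0.302). Without old replicate 2, oxidative phosphorylation (adjusted p = 0.00607) and mitochondrially encoded transcripts (adjusted p = 0.000303) were called lower and immediate early genes higher (adjusted p = 0.00391). Oxidative phosphorylation was also called lower without young replicate 3 (adjusted p = 0.0493) and, like mitochondrially encoded transcripts, under quantile normalization (adjusted p = 0.0135 and 0.0333), and the latter with array weights (adjusted p = 0.0452).

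Manf, a secreted protein of the ER stress response that work on macrophages in muscle repair has addressed, had 28.2, 22.02 and 18.3 FPKM in young and 26.3, 30.4 and 29.6 FPKM in old. Its log2 change was 0.34 (SE 0.15, limma adjusted p = 0.35), which did not pass, and the values of the groups overlapped. The exact permutation test gave p = 0.2, where 0.1 is the smallest p that 3 libraries per group allow. The log2 change of Manf was 0.20 without young replicate 3 (adjusted p = 0.651), within a range of 0.20 to 0.50 over the libraries left out.

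Genes of the gate and other surface markers did not pass over all genes. Itgam, which encodes CD11b, had 35.9 ± 1.36 and 47.4 ± 4.83 FPKM (0.39), and Adgre1 had 362 ± 17.6 and 446 ± 26.3 FPKM (0.30). Cx3cr1, which is not part of the gate, had 89.1 ± 11.2 and 63.6 ± 11.9 FPKM (-0.49). Ly6c2 had 3.2, 2.32 and 1.31 FPKM in young and 7.68, 2.46 and 6.99 FPKM in old (0.97), and Ly6c1 had 0.267 and 0.0677 FPKM. Itgam, Adgre1 and Ly6c2 were higher and Cx3cr1 lower over their list alone. The neutrophil gene Ly6g was listed at 0 in all libraries. Xist was at 21.3 to 30.2 FPKM in all 6 libraries, Tsix was at or below 0.01, and Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0.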

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

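The fit of voom to recovered fragments and the threshold of 0.1 were chosen after the data were seen. Genes passing (higher and lower in old) numbered 2 and 2 in the primary limma analysis and under median-of-ratios, quantile and TPM scaling and robust moderation, and 3 of the 4 calls were kept under TPM and all 4 under the others. They numbered 0 and 0 with pseudocounts of 0.1 and 0.01, without the filter and with a minimum of 5 FPKM (1665, 1658, 2489 and 1143 genes at an unadjusted p under 0.05), 3 and 1 without the trend, 30 and 20 with array weights, 27 and 15 with voom on recovered fragments, and 35 and 16 at a threshold of 0.1. Voom and array weights shared 30 of their genes. Leaving out 1 library gave 0 to 6 higher and 0 to 9 lower genes. The calls without young replicate 1 were 6 and 9, and those without any other library 0 and 0 (1085 to 1687 at an unadjusted p under 0.05). The cause of these differences was not tested.

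Lists called higher numbered 11 in the primary analysis, 9 to 13 without 1 library, 0 with an estimated correlation and 1 with fry. Lists called lower numbered 3, and 6 without the filter, 7 under quantile normalization, 8 with array weights, 5 with voom, 2 to 7 without 1 library, and 0 with an estimated correlation and with fry. Type I interferon, MHC class I, lysosome, phagocytosis, complement, ER stress, repair markers, resident macrophages and ribosomal proteins kept their camera calls under the 18 settings with the preset correlation. Of the lists not called in the primary analysis, 12 were called under at least 1 of them, most often MHC class II (6) and oxidative stress (5), both lower. The log2 change of Manf ranged from 0.20 to 0.50, both from leaving 1 library out, and its adjusted p from 0.133 to 0.651.

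With the replicate number as a replicate block, 0 genes were higher and 0 lower (1658 at an unadjusted p under 0.05), lists numbered 10 and 3, growth factors losing their call (adjusted p = 0.068), and Manf stayed at 0.34 (adjusted p = 0.394). Deviations of libraries with the same number correlated at only 0.032, 0.054 and 0.042. Each library correlated best with its own number, but correlations this small are no evidence of pairing, and the labels state none.

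Single genes were followed across settings for the genes of the naming rule, taken over every list, and the features outside it that passed, not for all 11108. Among these, 59 values became past the threshold under another setting, 40 fell below it, 2977 stayed on their side, and 6 changed sign, in genes that did not pass. Leaving out 1 library, Ccr3 ranged from -0.281 to 0.004 (without young replicate 1), Bpgm from -0.05 (without young replicate 2, and -0.034 without old replicate 1) to 0.135, Cd28 from -0.269 to 0.027 (without young replicate 3, and 0.006 without old replicate 1) and Vcam1 from -0.48 to 0.032 (without young replicate 3). Depth limits low genes most, as for Actc1 with 1 to 6 fragments in old.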

Other observations

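The tests of gene length, GC content, marker counts, equal depth, and monocyte and resident markers were chosen after the results they address were seen. The set of 5' TOP transcripts was also narrowed after a first value was seen. The tests of splits, ribosomal pseudogenes, 5' TOP transcripts and osteoclast-associated genes were written down before their values were computed.

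Genes known from osteoclasts, bone-resorbing cells of the same lineage, stood among the lower values in old. Acp5, Mmp9, Ocstamp and Mmp14, seen first, had log2 changes of -0.94, -2.29, -0.68 and -0.61. Of 11 further genes of that kind, 4 were lower by over 2 standard errors (Src at -0.72, Rab38 at -0.49, Ctsk at -0.48 and Nfatc1 at -0.28) and 1 higher (Clcn7 at 0.33). The median of the 11 was 0.033, inside the -0.08 to 0.138 of matched random lists. By the bound written beforehand this counts against a lower osteoclast-associated programme in old. The reading that members going both ways leave a median near 0 undecided was adopted after the value was seen. A lower level of part of these genes remains a hypothesis, which rests on members seen to be lower in these same libraries.

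Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 4 genes past the threshold and the highest other split 1, and 1 of the 10 gave as many as the real one, itself. At an unadjusted p under 0.05 it gave 1668 genes, the highest other 805, again with 1 split reaching the real value. For lists it gave 14 and the highest other 15, and 3 of the 10 splits gave 14 or more, the real one included.

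Lower ribosomal protein genes in old might be a shift along gene length or GC content, or fragments assigned to pseudogenes. Genes matched on length and expression had a median change of 0.059, and those matched on GC content and expression 0.083, against -0.26 for the ribosomal genes. The 287 pseudogenes with a ribosomal protein symbol did not gain what the genes had lost. Old minus young, they stood at -188.5 CPM and the ribosomal protein genes at -5482.1 CPM. Ribosomal pseudogenes under provisional symbols and fragments left uncounted were not examined, so a shift to those stays open. Other transcripts with a 5' TOP motif, which share translational control with ribosomal proteins, had a median of -0.179 over 24 genes, below the lower end (-0.026) of the range of matched random lists. A lower level of the whole class would give this median, as a hypothesis, while age, chance and other differences in sample handling stay open. The random lists were drawn gene by gene, so their range leaves out correlation between members of a class and can be too narrow.

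Less RNA of non-myeloid muscle cells in the old libraries could account for the lower muscle and stromal transcripts. Of 52 markers with at least 30 recovered fragments and under 5 FPKM in young, 47 were lower in old, 17 of 19 for muscle and 30 of 33 for stromal and vascular cells, with Flt1, Kdr, Tnfaip6, Ckm and Tcap the exceptions, and with 4 genes whose fragments were not whole (Pi16, higher, and Acta2, Notch3 and Actn3, lower) 50 of 56 were lower by FPKM. The share of lower genes among all genes within these limits was not computed, so the count cannot be read as particular to these cells. Some of the 52, such as Tnni2 and Sparc, had been seen lower before. Depth does not account for the lower number of detected genes, since at 16000000 fragments each, the old library with the most genes stood at -238 against the young one with the fewest (19552 and 19790). Summed markers overlapped between groups (222.8 to 311.3 CPM in young, 163.8 to 223.6 in old), and macrophages themselves express some of them, such as Vcam1 and Cspg4. The gate on CD11b and F4/80 should remove such cells, the most abundant fibre transcript, Acta1, had 5.26 FPKM in young, and uptake of debris and attached cells were not told apart.

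Higher monocyte and resident lists in old could come from carry-over of Ly6C-high monocytes or a larger share of resident macrophages, although the Ly6C-low gate should remove the former. Without interferon-responsive members (Ly6a, Ms4a4c, Plac8 and Ifi204), 13 monocyte markers had a median of 0.099, inside the -0.051 to 0.162 of matched random lists, and Ccr2 was at -0.55 (SE 0.231), while Ly6c2 was at 0.97. Of 8 resident markers with under 10 FPKM in young, 5 were higher by over 2 standard errors and 0 lower, but that limit on the young level favours markers higher in old and leaves out Selenop (-0.41, SE 0.184), so the count decides nothing. A larger share of resident macrophages and a changed state of the same cells stay open. In bulk libraries these cannot be told apart.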
